A study of Mus musculus with 7 samples.

How the data were processed

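The samples were primary ovarian granulosa cells of C57BL/6J mice, with 4 wild-type (WT) libraries and 3 libraries from mice labelled as Fhl2 knockout (Fhl2 KO), all without treatment. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with a stranded mRNA kit. Per the submitters' processing notes, the tools named were fastp, HISAT2 2.2.1, SAMtools, featureCounts 1.6.4, Cufflinks 2.2.1 and DESeq2 1.28.1, with genome build mm10 and with no role or order given. The gene annotation release and the strand setting of the read counting are not given in the sources used here. Without a stated strand setting, reads of a gene and of an antisense or overlapping gene may not be separated. The rule for reads shared between near-identical genes is not given either, so values of multigene families such as Hsd3b and Gsta carry that uncertainty.

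The deposited values were counts: whole-number read counts per gene symbol, 1 column per library and not normalized by the authors. The table had 55228 rows, of which 25188 had 0 counts in all 7 libraries. The total count per library ran from 38855596 to 50514556, so 3 counts, taken as the floor, correspond to 0.0594 to 0.0772 CPM, the count scaled by library total, per library. Such floors cover counting error only, since reads without molecular identifiers are not independent molecules. In 26 rows the gene name had been turned into a date, a known effect of spreadsheet software. These rows held 0.172% of all counts, 20 of them were tested, and none is named. The 4 rows that shared a name with another row were kept as separate rows. Gene coordinates, transcript lengths and GC content were taken from GENCODE release M21 of the same build, in which 96.8% of the rows had a unique symbol. Of the genes tested, 15574 (98.6%) had a length and a GC content.

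Library groups came from the sample labels. The labels do not say whether the libraries of a group came from separate animals or cultures, so p-values measure the spread between these samples, which may in part be technical. No pair of libraries held duplicated counts: the chi-square per degree of freedom between 2 libraries of a group was at least 10.4.

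Genes were tested in R 4.3.3 with edgeR 4.0.16 (filterByExpr with its default minimum count of 10, TMM scaling, glmQLFit with robust estimation and glmQLFTest), with genotype as the only term, and p-values were adjusted by the Benjamini-Hochberg method over the 15798 genes tested. The genes not tested held 0.0511% of the counts. Fold changes are Fhl2 KO over WT, standard errors (SE) are on the log2 scale and were derived from the F statistic, and levels are CPM scaled by TMM, given as mean ± SD. A gene was called past adjusted p 0.05, and a separate count required an absolute log2 fold change of at least 1. Of 32 gene lists fixed by name, each with at least 3 members tested, all were tested with camera (limma 3.58.1, log2 CPM with a prior count of 2, inter-gene correlation preset at 0.01), adjusted over the lists. For each list the calls are given over all genes tested and adjusted over the list alone. Camera was also run with a correlation estimated per list, and fry tested each list without reference to other genes.

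The groups, the tests, the lists, the rule for named genes and most of the alternative settings were fixed before the data were examined. The named genes were Fhl2 and its family. Added to these were the 12 genes with the largest rise and the 12 with the largest fall among genes past adjusted p 0.05. Those genes also needed KO libraries lying all above or all below the WT libraries and a mean of at least 1 CPM, and predicted-gene names were left out. From each list, up to 4 members with the smallest p were named. Some genes that the rule covers are not reported here. Genes named outside this rule were chosen after their values were seen, and are identified as such.

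Alternative settings fixed in this way were DESeq2 1.42.0, limma voom with sample quality weights, median-of-ratios size factors, library totals alone, no low-count filter, and a filter of at least 10 CPM in 3 libraries. Others were the replicate number as a block, the same 6 libraries without it, each library left out in turn, removal of mitochondrial, ribosomal protein and predicted genes, no robust estimation, 1 surrogate variable (sva 3.50.0), fry, and camera with an estimated correlation. Alternatives chosen after seeing the data were a correction for transcript length and GC content, the same with camera's correlation estimated, a correction for length alone, KO library 1 alone against WT, and removal of 12 lung genes. In the correction, each library's smooth trend of log2 CPM on length and GC (natural splines with 4 degrees of freedom, fitted on genes above 1 CPM) entered edgeR as an offset. The lone KO library was assumed to vary like the WT libraries.

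The steps were tested on simulated data drawn from the means and library sizes of the Fhl2 KO against WT comparison. Among 15562 simulated genes tested, the test recovered 89.6% of 67 genes changed 1.5-fold, 100% of 67 changed 2-fold and 100% of 66 changed 4-fold, with 12 false calls among 205. With a simulated length and GC trend over 15583 genes, 535 of 721 calls were false, against 19 of 206 after the correction. The simulated trend was drawn from the same spline model that the correction fits, so its removal was built in. The simulation does not show how the correction handles a trend of another form, or an effect of genotype that follows length. In a simulation of the 32 lists, the list shifted by 0.5 on the log2 scale was called, as was 1 of the 29 lists sharing no gene with it. The simulated genes were drawn independently of each other. The simulation therefore does not show how camera with the preset correlation handles lists whose members vary together.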

Results

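Granulosa cells are the somatic cells that surround the oocyte in the ovarian follicle and make estradiol and, after ovulation, progesterone. Read counts per gene were available for primary granulosa cells of WT mice (4 libraries) and of mice labelled as Fhl2 knockout (Fhl2 KO, 3 libraries). FHL2 is a LIM-domain protein that binds transcription factors and cytoskeletal proteins. The series title names follicle growth and EGF receptor and YAP signalling as the subjects of the study. The WT libraries 1 to 4 held 39007770, 50514556, 47820917 and 44267549 counts, and the KO libraries 1 to 3 held 38855596, 45323309 and 45455488. Across genes, log2 CPM correlated between libraries of the WT group at Pearson r of 0.989 to 0.990 and between KO libraries at 0.983 to 0.987. The first principal component held 41.8% of the variance and separated the genotypes. The libraries ranked on it in the same order as by their dependence on transcript length, given below. It therefore cannot be told apart from that trend. KO library 1 lay between the others, at 10.6 on that component against 47.1 and 38.2 for KO libraries 2 and 3 and -27.1 to -18.6 for the WT libraries.

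Fhl2 itself was examined in every library to check the labels. It had 3910, 5732, 4958 and 4798 counts in WT libraries 1 to 4 and 1880, 3132 and 2749 counts in KO libraries 1 to 3. The level was 107.8 ± 5.63 CPM in WT (SD, n = 4) and 58.4 ± 9.57 CPM in KO (SD, n = 3), or 54.1% of WT. Fhl2 fell by 0.88 on the log2 scale (SE 0.107, edgeR adjusted p = 3.29e-05) and was lower in each of the 3 KO libraries than in any WT library. Reads of the gene thus remained in each KO library, and a count per gene does not show which exons they cover. The gene lies on the minus strand of chromosome 1 from 43123074 to 43196984 (mm10). Of its family, Fhl1 (log2 fold change -0.17, SE 0.0876, edgeR adjusted p = 0.155), Fhl3 (-0.07, SE 0.112, 0.695) and Fhl4 (0.40, SE 0.506, 0.595) did not pass the test. Fhl5 had 0 counts in all 7 libraries. The FHL family list includes the targeted gene itself, so its test cannot show a shift of the other members alone. It had 1 of 4 members lower, Fhl2, also adjusted over the list alone, and was not past the threshold (median -0.12, camera adjusted p = 0.258). It passed after the correction for length and GC content described below (median -0.24, camera adjusted p = 0.0294) and for KO library 1 alone (0.00397), within a range of 0.00397 to 0.468 over its alternatives, but with adjusted p = 0.334 and 0.173 with an estimated correlation. Fhl3 passed after that correction as well (-0.29, edgeR adjusted p = 0.0382; range 0.0382 to 0.918). Among 16 tested genes next to Fhl2 on chromosome 1, 1 was higher, also adjusted over the list alone, and the list did not pass (median -0.13, corrected -0.08, camera adjusted p = 0.585). That gene was Rpl31 (0.33, corrected 0.14), whose call was lost without KO library 3 (edgeR adjusted p = 0.0736) and under the length and GC correction (0.116, with a range of 8.22e-05 to 0.395 over its alternatives).

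**Figure D1:**
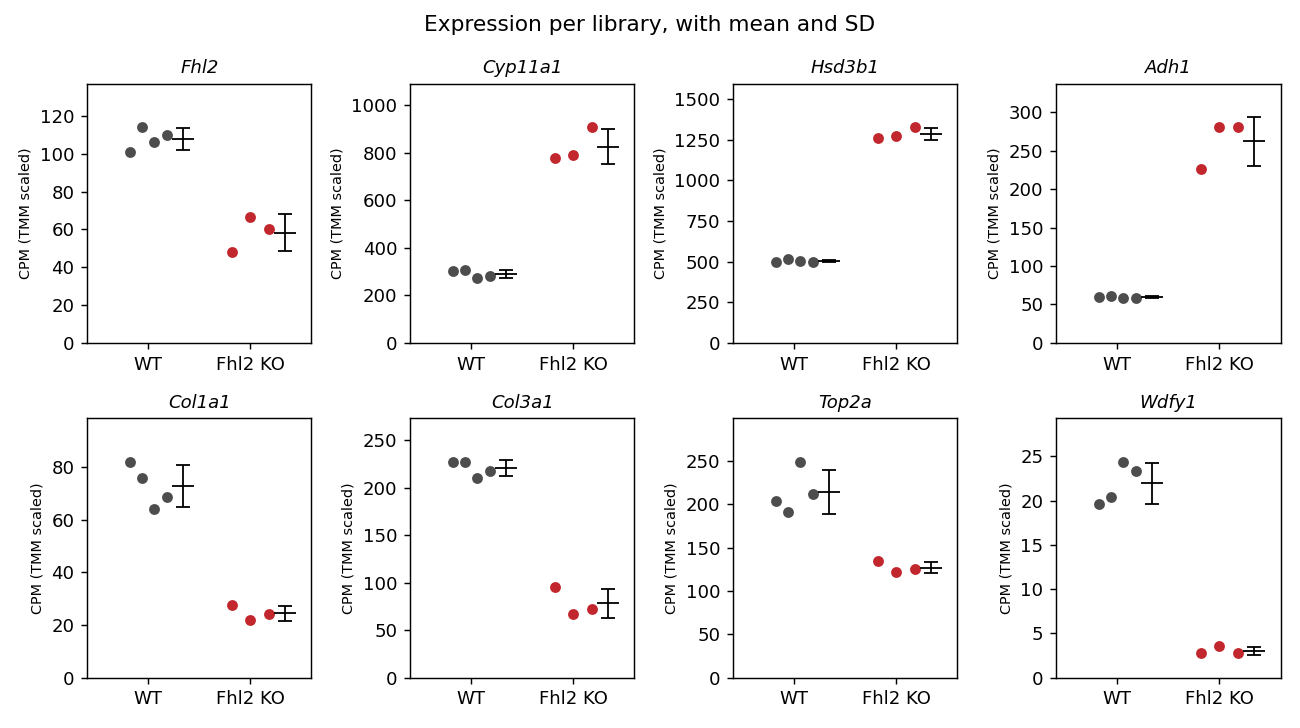
Expression of 8 genes in CPM (TMM scaled, linear axes from 0) in 4 WT (grey) and 3 Fhl2 KO (red) libraries; each point is a library, in the order of its number, and the bars beside the points give mean and SD. Fhl2 averaged 107.8 CPM in WT and 58.4 CPM in KO, and in each panel the KO points lie all above or all below the WT points.

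The question of the main comparison was which genes and gene groups differ between granulosa cells of the WT and Fhl2 KO mice. In the KO libraries, Cyp11a1, the enzyme that turns cholesterol into pregnenolone, rose 2.83-fold (SE 0.0913 on the log2 scale), and Hsd3b1, which makes progesterone from pregnenolone, rose 2.55-fold (SE 0.0828; n = 4 WT and 3 KO). Col1a1, the gene of a fibrillar collagen chain, fell from 72.7 ± 7.87 CPM in WT (SD, n = 4) to 24.5 ± 2.91 in KO (SD, n = 3). Of 15798 genes tested with edgeR, 4588 (29.0%) passed, 2128 higher and 2460 lower in KO, and 335 of them changed at least 2-fold (158 higher, 177 lower). The balance turned when libraries were scaled by their totals alone, with 2630 genes higher and 2129 lower, and 179 and 155 at 2-fold. For all calls, the balance also turned under the corrections described below, for length and GC (1925 higher, 1785 lower) and for length alone (1652 and 1544). At 2-fold it also turned with no low-count filter (220 higher, 203 lower) and for KO library 1 alone against WT (69 and 66). The libraries of the groups did not overlap for 34.2% of genes, where chance gives 5.71%. The count was 1657 without KO library 3, 2994 without WT library 3, 2960 without WT library 4 and 781 for KO library 1 alone against WT; the 2-fold count was 579 without KO library 1, 536 with voom quality weights, 135 for KO library 1 alone and 79 with a filter of 10 CPM.

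Among the 12 genes with the largest rise were the alcohol and retinol dehydrogenases Adh1 and Adh7 and the glutathione S-transferases Gsta2 and Gstm6, members of families with near-identical copies. Adh1 went from 59.6 ± 1.52 CPM in WT (SD, n = 4) to 262.5 ± 31.8 in KO (SD, n = 3; log2 fold change 2.14, SE 0.0947, edgeR adjusted p = 2.55e-10), and Adh7 rose 5.66-fold (SE 0.192 on the log2 scale). The ectonucleotidase Nt5e (1.92, SE 0.126), the serotonin transporter Slc6a4 (2.14, SE 0.190), Mro (1.76, SE 0.154) and the keratin Krt7 (2.41, SE 0.222) also rose. Sftpc and Sftpb, known as surfactant genes of the lung, headed the list with 121, 409 and 12 reads and 110, 289 and 18 reads in KO libraries 1 to 3, and with at most 4 reads in any WT library. The chemokines Cxcl1 and Cxcl2 completed it. Cxcl1 stood at 52.6, 438.5 and 637.6 CPM in KO libraries 1 to 3 and at 42.9 ± 5.13 CPM in WT (SD, n = 4). The call of Cxcl1 was lost without WT library 1, 2, 3 or 4 or KO library 2 or 3 (edgeR adjusted p of 0.0942 to 0.137) and that of Cxcl2 without the same libraries (0.0514 to 0.0793), while that of Sftpc was lost without WT library 1, 2, 3 or 4 (0.0800 to 0.217). With no low-count filter the edgeR adjusted p was 0.0746 for Cxcl1 and 0.0576 for Sftpc, and under a correction for length alone it was 0.0561 for Cxcl1. The lowest edgeR adjusted p of Cxcl2 (6.56e-51) and of Sftpc (1.16e-37) came with the replicate number as a block. The same setting gave the highest for Cxcl1 (0.335), and the counts gave no sign that these numbers pair the samples. Over all alternatives the edgeR, DESeq2 or limma adjusted p ranged from 2.53e-07 to 0.335 for Cxcl1, from 6.56e-51 to 0.204 for Cxcl2 and from 1.16e-37 to 0.217 for Sftpc.

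Among the 12 genes with the largest fall, Wdfy1, an endosomal protein gene on chromosome 1 from 79702262 to 79776143, went from 22.0 ± 2.29 CPM in WT (SD, n = 4) to 3.05 ± 0.442 in KO (SD, n = 3; log2 fold change -2.84, SE 0.140, edgeR adjusted p = 7.43e-10). Smooth-muscle myosin Myh11 (-2.11, SE 0.169), the collagen chains Col1a2 (-1.72, SE 0.146) and Col1a1 (-1.57, SE 0.112), and the pericyte proteoglycan Cspg4 (-1.58, SE 0.352) fell as well. The others were Sv2c (-2.36), Nalcn (-1.83), Fgl2 (-1.78), Casq2 (-1.73), Cxcl5 (-1.73), Scube2 (-1.65) and Nhsl2 (-1.63, or -1.07 after the length and GC correction described below).

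The libraries also differed in how levels depended on transcript length. Relative to the mean of all libraries, log2 CPM changed per doubling of length by 0.0584 to 0.0855 in the WT libraries, by -0.00154 in KO library 1, by -0.170 in KO library 2 and by -0.133 in KO library 3. With genes in 10 bins by transcript length, the median log2 fold change was 0.30 and 37.8% of genes rose in the bin of the shortest transcripts, whereas in the bin of the longest it was -0.39 and 50.6% fell. After a correction for length and GC content, chosen after seeing the data, 3710 genes passed with edgeR (1925 higher, 1785 lower), 261 of them at least 2-fold, and 2591 of the 4588 calls (56.5%) were kept in the same direction. Values after this correction are given below as corrected values.

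KO library 1 alone against WT, a setting with fewer samples chosen after seeing the data, lost the calls of 41 of the 113 named genes past the threshold. Of the genes given here, these were Cxcl1, Cxcl2, Gstm6, Scube2, Cspg4, Amot, Tead1, Taok1, Sos1, Egf, Egfr, Shc1, Phlda1, Junb, Lss, Cyp51, Mcm4, Bax, Cdkn1a, Cxcl10, Bst2, Hsph1, mt-Nd3, mt-Co3, mt-Nd4l, Rpl31, Pdgfra, Bmp15, Krt18 and Krt19. In that setting Myof was at -0.36, Wwc1 at -0.46, Runx2 at -0.46, Tpx2 at -0.49 and Actn1 at -0.58 on the log2 scale, still past the threshold. The list medians there were -0.13 for Hippo components, -0.15 for actin, -0.32 for matrix and 0.22 for steroid synthesis genes. For surface epithelium genes the median was 0.81 over the members tested in that setting and 1.15 over those tested in the main fit.

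**Figure D2:**
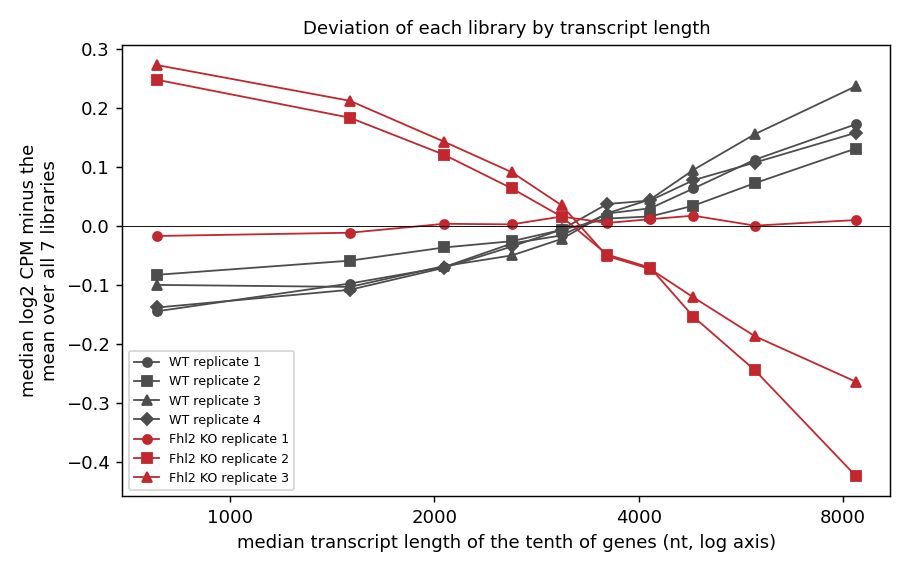
Median deviation of log2 CPM from the mean over all 7 libraries (vertical axis) in 10 bins of genes ordered by transcript length (horizontal log axis, nt), 1 line per library (WT grey, Fhl2 KO red). In the bin of the longest transcripts the 4 WT libraries lie between 0.13 and 0.24, KO library 1 at 0.01 and KO libraries 2 and 3 at -0.42 and -0.26.

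Genes of steroid synthesis and luteal markers were higher in KO. Of 16 tested steroid synthesis genes, 9 rose, 1 fell and 6 did not pass (9 higher and 3 lower adjusted over the list alone). The list was higher (median 0.37, corrected 0.24, camera adjusted p = 4.07e-04), with adjusted p = 0.138 with an estimated correlation. Cyp11a1 went from 291.5 ± 16.6 CPM in WT (SD, n = 4) to 825.6 ± 72.9 in KO (SD, n = 3; edgeR adjusted p = 1.57e-08) and lies on chromosome 9 from 58006411 to 58027023. Hsd3b1, on chromosome 3 from 98852194 to 98859794, went from 504.0 ± 6.88 to 1286 ± 37.0 CPM (log2 fold change 1.35, SE 0.0828, edgeR adjusted p = 1.57e-08), and Fdx1, the ferredoxin that passes electrons to mitochondrial P450 enzymes, rose by 0.87 (SE 0.0869). Akr1c18, which breaks progesterone down, rose from 0.104 ± 0.0370 CPM, near the floor, to 1.56 ± 0.307 CPM. The member that fell was Nr5a2, a nuclear receptor of steroid synthesis (edgeR adjusted p = 0.0329, corrected 0.378), named after its value was seen. Of 12 tested luteal markers, 8 rose, also adjusted over the list alone, and none fell. The list was higher (median 0.55, corrected 0.68, camera adjusted p = 1.32e-06), with adjusted p = 0.0971 with an estimated correlation. It shares Cyp11a1, Hsd3b1, Akr1c18, Star and Scarb1, a lipoprotein receptor that rose by 0.81 (SE 0.0875), with the steroid list. Ptgfr, the prostaglandin F receptor, named after its value was seen, had 0 counts in all 4 WT libraries and was at least 53.3-fold higher in KO against a floor of 3 counts over the WT group, and with it at that bound the list's median stayed at 0.55.

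Genes of cholesterol synthesis and uptake were lower: of 25 tested, 10 fell, 1 rose and 14 did not pass (12 lower and 1 higher adjusted over the list alone; median -0.17, corrected -0.18). Camera gave adjusted p = 0.0116, and adjusted p = 0.202 with an estimated correlation. Sqle fell by 0.51 (SE 0.0893, n = 4 WT and 3 KO; corrected -0.33) and Cyp51 by 0.37 (SE 0.0877) on the log2 scale, both enzymes of sterol synthesis, and Lss fell by 0.55 (SE 0.105; corrected -0.20, edgeR adjusted p = 0.114, range 1.80e-05 to 0.114). The member that rose was the sterol isomerase Ebp (edgeR adjusted p = 0.0454), named after its value was seen. The call of this list was lost without KO library 1 (camera adjusted p = 0.0783), with voom quality weights (0.0526) and with the filter of 10 CPM (0.0526), within a range of 1.02e-04 to 0.0783 over its alternatives.

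Granulosa cell identity genes moved in both directions. Of 23 tested, 6 rose, 10 fell and 7 did not pass (7 higher and 10 lower adjusted over the list alone), and the list did not pass (median -0.15, corrected -0.13, camera adjusted p = 0.310). Kitl, the ligand of the oocyte's KIT receptor, rose from 85.9 ± 8.53 to 150.2 ± 16.7 CPM, and the inhibin alpha subunit Inha rose from 1042 ± 53.5 to 1699 ± 121 CPM (log2 fold change 0.71, corrected 0.47). The inhibin beta B subunit Inhbb fell from 388.9 ± 34.2 to 228.8 ± 26.8 CPM and Igf1 from 426.7 ± 37.7 to 293.6 ± 13.2 CPM (SD, n = 4 WT and 3 KO). The change of Igf1 was -0.54 (corrected -0.25), and its call was lost under the correction for length alone (edgeR adjusted p = 0.0868, range 3.48e-07 to 0.0868). Of 20 tested ovulation and luteinization genes, 5 rose and 6 fell (6 and 6 adjusted over the list alone), and the list did not pass (median 0.15, camera adjusted p = 0.444). The coactivator Cited4 rose by 1.30 (SE 0.140), Star, which carries cholesterol into mitochondria, rose by 0.69 (SE 0.108), and the transcription factor Runx2 fell by 0.71 (SE 0.108; corrected -0.41) on the log2 scale. Corrected for length and GC, that list passed (median 0.35, camera adjusted p = 0.0259; range 0.0259 to 0.552 over its alternatives), with adjusted p = 0.238 with an estimated correlation. Of 8 tested theca cell markers, 3 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.520). The median of that list was -0.07 (corrected -0.04) while its mean was 0.05 and its test pointed upward. Its members that rose were Fdx1, Star and Aldh1a1, and Ptch1, the hedgehog receptor, fell by 0.54 (SE 0.0945; corrected -0.07, edgeR adjusted p = 0.607, range 3.21e-06 to 0.607). The Aldh1a1 call was lost without WT library 1 (edgeR adjusted p = 0.0550) and without KO library 3 (0.0606) and under the correction for length alone (0.0549), with a range of 6.00e-04 to 0.0764 over its alternatives.

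Genes of the extracellular matrix and of contractile cells were lower in KO. Of 37 tested extracellular matrix genes, 25 fell, 2 rose and 10 did not pass (27 lower and 2 higher adjusted over the list alone). The list was lower (median -0.55, corrected -0.39, camera adjusted p = 6.30e-12), with adjusted p = 0.215 with an estimated correlation. Besides Col1a1, on chromosome 11 from 94936224 to 94953042, Col3a1 fell and went from 220.7 ± 8.38 CPM in WT (SD, n = 4) to 78.2 ± 14.9 in KO (SD, n = 3; SE 0.112 on the log2 scale, edgeR adjusted p = 1.81e-07). The collagen cross-linking enzyme Lox went from 668.3 ± 49.0 to 329.4 ± 20.1 CPM, and the basement membrane protein Nid1 from 20.6 ± 1.06 to 8.67 ± 0.768 CPM. The members that rose were Timp1 (edgeR adjusted p = 0.00902, corrected 0.157) and Timp3 (0.0348), inhibitors of matrix-degrading proteases, named after their values were seen. Of 11 tested stroma and fibroblast markers, 7 fell and none rose (8 lower adjusted over the list alone; median -0.78, corrected -0.91, camera adjusted p = 1.22e-04), with adjusted p = 0.0971 with an estimated correlation. Its median was -1.52 with the filter of 10 CPM. It shares Col1a1, Col1a2, Col3a1, Dcn and Lum with the matrix list, and its receptor Pdgfra fell by 0.78 (SE 0.154, corrected -0.43). Decorin (Dcn), an abundant transcript of fibroblasts, stood at 0.517 ± 0.0678 CPM in WT and 0.691 ± 0.163 in KO.

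Of 34 tested genes of the actin cytoskeleton and focal adhesions, 13 fell, 3 rose and 18 did not pass (18 lower and 5 higher adjusted over the list alone; median -0.23, corrected -0.23, camera adjusted p = 1.22e-04), with adjusted p = 0.0971 with an estimated correlation. The integrin subunit Itgav went from 205.8 ± 3.26 CPM in WT (SD, n = 4) to 105.8 ± 4.58 in KO (SD, n = 3; log2 fold change -0.96, corrected -0.61), smooth-muscle actin Acta2 from 882.1 ± 38.1 to 490.7 ± 40.4, tropomyosin Tpm1 from 4005 ± 222 to 2512 ± 222 and the actin crosslinker Actn1 from 379.4 ± 15.8 to 198.9 ± 49.6. The members that rose were Actb (edgeR adjusted p = 0.0366, corrected 0.140) and Actg1 (0.0361, corrected 0.193), the cytoplasmic actins, and the adhesion protein Zyx (0.0240), named after their values were seen. Of 8 tested smooth muscle and pericyte markers, 5 fell and none rose, also adjusted over the list alone (median -0.64, corrected -0.72, camera adjusted p = 1.31e-04), with adjusted p = 0.0971 with an estimated correlation. Besides Myh11, Acta2 and Cspg4, calponin Cnn1 fell by 1.07 on the log2 scale (SE 0.188). The smooth muscle list shares Acta2 and Cnn1 with the actin list.

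**Figure D3:**
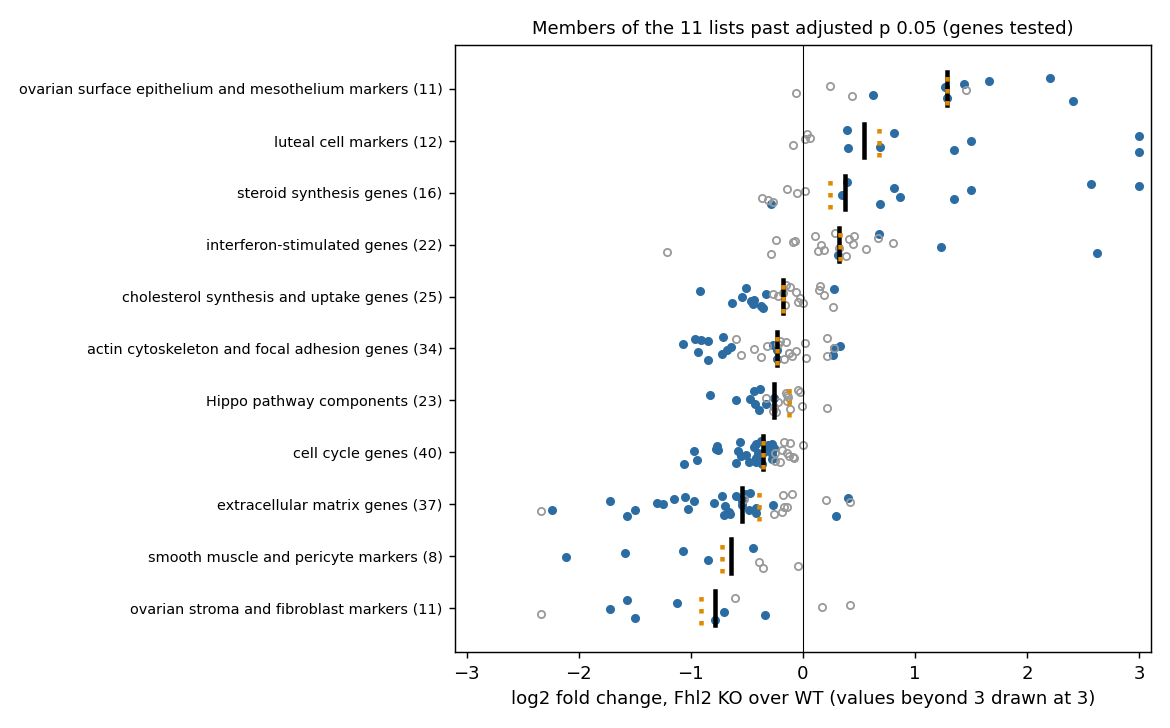
Log2 fold change of each tested member (points) of the 11 gene lists past adjusted p 0.05 with camera, with genes past adjusted p 0.05 filled and others open; black bars give the list medians and dotted orange bars the medians after the length and GC correction. The median of extracellular matrix genes was -0.55 and -0.39 after the correction, and that of Hippo pathway components -0.26 and -0.12.

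Cell cycle genes were lower in KO. Of 40 tested, 29 fell, none rose and 11 did not pass (31 lower adjusted over the list alone). The list was lower (median -0.36, corrected -0.36, camera adjusted p = 1.34e-11), with adjusted p = 0.138 with an estimated correlation. Topoisomerase Top2a went from 214.3 ± 24.9 CPM in WT (SD, n = 4) to 126.9 ± 6.67 in KO (SD, n = 3), and the spindle protein Tpx2 from 109.4 ± 5.92 to 63.8 ± 12.3 CPM. The mitotic kinesin Kif11 fell by 0.76 (SE 0.111) and the replication helicase subunit Mcm4 by 0.59 (SE 0.106) on the log2 scale. Apoptosis and atresia genes did not pass as a list, with 6 of 25 higher and 3 lower, also adjusted over the list alone (median 0.09, corrected 0.11, camera adjusted p = 0.307). Both pro-survival and pro-death members rose: Bcl2l1, which blocks apoptosis, rose by 0.47 (SE 0.0883) and Bax, which drives it, by 0.53 (SE 0.119; corrected 0.27), while the pro-survival Bcl2 fell by 0.82 (SE 0.152; corrected -0.44). Among 20 tested p53 target genes, 5 rose and 2 fell, also adjusted over the list alone (median 0.11, corrected 0.16, camera adjusted p = 0.173). Cdkn1a, an inhibitor of the cell cycle, rose by 0.34 (SE 0.0930), a call lost without KO library 3 (edgeR adjusted p = 0.0645) and under the length and GC correction (0.18, edgeR adjusted p = 0.0861; range 0.00192 to 0.155 over its alternatives).

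For the signalling named in the title, the lists gave mixed directions. Of 18 tested EGF ligands, receptors and adaptors, 2 rose, 4 fell and 12 did not pass, also adjusted over the list alone (median -0.01, corrected 0.13, camera adjusted p = 0.560). Egf fell by 1.31 (SE 0.295), from 1.86 ± 0.314 CPM in WT (SD, n = 4) to 0.751 ± 0.265 in KO (SD, n = 3). Egfr went from 29.9 ± 0.942 to 21.7 ± 3.58 CPM, a fall of 0.46 (SE 0.109, edgeR adjusted p = 0.00590). After the length and GC correction Egfr stood at -0.01 (edgeR adjusted p = 0.933), and without KO library 3 its adjusted p was 0.0530, within a range of 6.05e-05 to 0.933 over its alternatives. The exchange factor Sos1 fell by 0.50 (SE 0.0969; corrected -0.12, edgeR adjusted p = 0.203, range 3.42e-05 to 0.353). The members that rose were Shc1, an adaptor (0.33, SE 0.0904; lost without KO library 3 at edgeR adjusted p = 0.0825, range 2.13e-04 to 0.383), and the ligand Hbegf, named after its value was seen.

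Of 23 ERK-responsive immediate early and feedback genes, 7 rose, 2 fell and 14 did not pass, also adjusted over the list alone. The list did not pass (median 0.22, corrected 0.13, camera adjusted p = 0.0603), but passed under some alternatives, among them DESeq2 (0.0273), no low-count filter (0.0344), KO library 1 alone (0.00144) and the omission of WT library 2 (0.0409), WT library 4 (0.00370), KO library 2 (0.0314) or KO library 3 (0.0149), within a range of 3.22e-04 to 0.289 over its alternatives. With an estimated correlation these settings, DESeq2 aside, gave adjusted p of 0.410 to 0.646. The median was 0.12 without WT library 3. The phosphatase Dusp4, which turns ERK off, went from 108.7 ± 9.68 CPM in WT (SD, n = 4) to 214.0 ± 42.5 in KO (SD, n = 3). Phlda1 rose by 0.85 (SE 0.123), Fosl1 by 1.57 (SE 0.311) and Junb by 0.64 (SE 0.131), the latter pair being parts of the transcription factor AP-1. Junb stood at 292.5, 403.0 and 469.8 CPM in KO libraries 1 to 3, and with KO library 1 alone it was at 0.23 (edgeR adjusted p = 0.195, range 6.04e-09 to 0.195) and Phlda1 at 0.88 (0.0778, range 1.09e-14 to 0.0778).

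Of 20 tested YAP target genes, 4 rose, 5 fell and 11 did not pass, also adjusted over the list alone, and the list did not pass (camera adjusted p = 0.983). Its median was -0.01 (corrected 0.09) and its test pointed downward, while its mean was 0.03. Nt5e and Ankrd1, a stretch-responsive gene (80.4 ± 11.6 CPM in WT, SD, n = 4, and 108.5 ± 9.74 in KO, SD, n = 3), rose, and Myof fell from 226.6 ± 9.22 to 140.1 ± 37.1 CPM (log2 fold change -0.69, corrected -0.36). The call of Ankrd1 was lost under the correction for length alone (edgeR adjusted p = 0.0533, range 3.12e-04 to 0.0533). Rbms3 fell by 0.48 (SE 0.0964; corrected -0.11, edgeR adjusted p = 0.341, range 1.16e-04 to 0.423). Of 23 Hippo pathway components, which act upstream of and together with YAP, 9 fell, none rose and 14 did not pass (12 lower and 1 higher adjusted over the list alone). The list was lower (median -0.26, camera adjusted p = 4.07e-04), with adjusted p = 0.346 with an estimated correlation. The call was lost under the length and GC correction (median -0.12, camera adjusted p = 0.152; range 1.00e-06 to 0.199 over its alternatives). Wwc1, the gene of the upstream regulator KIBRA, went from 100.1 ± 4.66 to 56.3 ± 14.8 CPM (corrected -0.76). The YAP partner Tead1 fell by 0.47 (SE 0.108; corrected -0.02, edgeR adjusted p = 0.857, range 4.47e-05 to 0.857), and Amot fell by 0.44 (SE 0.0945; corrected -0.08, edgeR adjusted p = 0.549, range 3.45e-04 to 0.549).

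Markers of the surface epithelium were higher in KO. Of 11 tested, 7 rose and none fell (9 higher adjusted over the list alone; median 1.3, corrected 1.3, camera adjusted p = 1.22e-04), with adjusted p = 0.202 with an estimated correlation. The median was 0.85 with DESeq2 and 0.82 with no low-count filter. Krt7 went from 1.86 ± 0.521 CPM in WT (SD, n = 4) to 9.98 ± 2.89 in KO (SD, n = 3), Krt19 from 1.05 ± 0.251 to 3.32 ± 0.945 and Krt18 from 33.7 ± 3.18 to 51.9 ± 8.64 CPM (log2 fold change 0.62, corrected 0.38). Interferon-stimulated genes were higher as a list, with 4 of 22 higher, also adjusted over the list alone, and none lower (median 0.32, corrected 0.33, camera adjusted p = 0.0248), and with adjusted p = 0.270 with an estimated correlation. That call was lost without KO library 1 (camera adjusted p = 0.101) and with the filter of 10 CPM (0.0758), within a range of 0.00337 to 0.101 over its alternatives, and the median was 0.51 without WT library 3. Usp18, a brake on interferon signalling, rose by 1.23 (SE 0.170) and Oasl2 by 0.68 (SE 0.102). The others were Cxcl10, lost without KO library 3 (edgeR adjusted p = 0.0799), and Bst2, lost without WT library 1, 3 or 4 or KO library 3 (0.0756 to 0.265). Over their alternatives the adjusted p ranged from 1.61e-05 to 0.542 for Cxcl10 and from 6.64e-04 to 0.949, the value after the length and GC correction, for Bst2.

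Other signalling and stress lists did not pass. Among 29 tested TGF-beta and BMP pathway genes, 6 rose and 9 fell (6 higher and 10 lower adjusted over the list alone; median -0.05, corrected 0.15, camera adjusted p = 0.980). The inhibitors of differentiation Id2 (220.8 ± 10.6 CPM in WT, SD, n = 4, and 506.6 ± 75.7 in KO, SD, n = 3), Id3 (log2 fold change 0.75, SE 0.0840, corrected 0.50) and Id1 (0.66, SE 0.0922, corrected 0.40), known targets of BMP signalling, rose together with the inhibitory Smad6 (0.54, SE 0.0859). Among 16 tested Wnt and beta-catenin target genes, 4 rose and 7 fell (4 and 8 adjusted over the list alone; median -0.30, corrected -0.20, camera adjusted p = 0.405). Wnt4 fell by 0.66 (SE 0.107) and the feedback gene Axin2 rose by 0.87 (SE 0.182). Among 14 tested inflammatory and NF-kB target genes, 5 rose and 3 fell (7 and 3 adjusted over the list alone; median 0.35, corrected 0.31, camera adjusted p = 0.173). The chemokine Cxcl12 rose from 117.4 ± 2.69 CPM in WT (SD, n = 4) to 208.6 ± 15.9 in KO (SD, n = 3), and the nitric oxide synthase Nos2 fell from 46.8 ± 5.88 to 17.7 ± 2.63 CPM. This list passed under some alternatives, among them without KO library 1 (median 0.73, camera adjusted p = 0.0151) and with no low-count filter (1.05, 0.00277), within a range of 7.59e-07 to 0.336 over its alternatives; with an estimated correlation the adjusted p was 0.374 and 0.155. Its median was 1.08 with DESeq2, 0.63 without KO library 3, 0.54 with the filter of 10 CPM and 0.21 for KO library 1 alone, without a call. Among 25 hypoxia and glycolysis genes, 6 rose and 2 fell (median 0.19, corrected 0.01, camera adjusted p = 0.128), and among 24 heat shock and unfolded protein genes 4 rose and 5 fell (median 0.10, corrected 0.01, camera adjusted p = 0.585), each also adjusted over the list alone. The hypoxia list passed with voom quality weights (camera adjusted p = 0.0472; range 0.0472 to 0.449), with adjusted p = 0.553 with an estimated correlation. Of these, the vasodilator peptide gene Adm rose by 0.81 (SE 0.118) and the chaperone Hsph1 fell by 0.52 (SE 0.105; corrected -0.32).

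Among 13 mitochondrially encoded mRNAs, 2 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.983). The median was -0.12, while the mean was 0.07 and the test pointed upward. After the length and GC correction the list was lower (median -0.40, camera adjusted p = 0.00187; range 0.00187 to 0.989 over its alternatives), with adjusted p = 0.338 with an estimated correlation. The members that rose were mt-Nd3 (1.68, SE 0.232) and mt-Co3 (0.44, SE 0.0989; corrected 0.17, edgeR adjusted p = 0.162, range 2.21e-05 to 0.162). The member that fell was mt-Nd4l (-0.40, SE 0.108, corrected -0.64), whose call was lost without WT library 3 (edgeR adjusted p = 0.0515) and without KO library 3 (0.0946), within a range of 5.00e-04 to 0.300 over its alternatives.

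Markers of most other cell types were low and did not pass as lists. None of 15 macrophage and leukocyte markers (median -0.01, corrected -0.14, but mean 0.02 and test pointing upward, camera adjusted p = 0.980) and none of 3 red blood cell markers (median 0.18, corrected -0.04, camera adjusted p = 0.585) passed, also adjusted over the list alone. Of 9 endothelial markers, Erg fell, from 1.02 ± 0.117 CPM in WT (SD, n = 4) to 0.192 ± 0.109 in KO (SD, n = 3), also adjusted over the list alone (list median -0.01, corrected -0.18, camera adjusted p = 0.654). Of 15 oocyte markers, Bmp15 was lower and none passed adjusted over the list alone (list median 0.02, corrected -0.10, camera adjusted p = 0.980). The Bmp15 call was lost without KO library 2 (edgeR adjusted p = 0.0818), without KO library 3 (0.130) and with voom quality weights (0.0549), within a range of 0.00897 to 0.476 over its alternatives. The oocyte list passed for KO library 1 alone against WT (median 0.54, camera adjusted p = 0.00799; range 0.00799 to 0.989 over its alternatives), with adjusted p = 0.564 with an estimated correlation. Of 5 nerve and glia markers, 2 rose and 1 fell, also adjusted over the list alone, among them Tubb3 (0.69, SE 0.0945) and Ncam1 (-0.79, SE 0.126, corrected -0.48) (list median 0.14, corrected 0.31, camera adjusted p = 0.377). With an estimated correlation, camera called 0 of the 32 lists, the smallest adjusted p being 0.0971, against 11 with the preset one; 12 lists lay under an unadjusted p of 0.05 with the preset one, and fry called 17. After the length and GC correction, 6 lists passed with an estimated correlation, those of actin and luteal genes (adjusted p = 0.0422) and of cell cycle, matrix, stroma and smooth muscle genes (0.0442), and 13 with the preset one.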

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

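Of the tests given here, that of the Fhl2 region and that of the lung genes were set before their results were seen; those of the length trend, the stromal genes, Nnt and the keratins, and the minimum of 20 reads for a lung gene, were chosen afterwards. In 5 of 139 sets of WT values, for the named genes and library measures, 1 WT library lay far from the other 3 by Dixon's test, which chance gives in about 1 of 20 sets. Sftpc was at 0.103 CPM in WT library 1 and at 0 in the others. Kif11 was at 59.3 CPM in WT library 3 against 44.0 to 46.0 in the others, and Id3 at 226.6 CPM in WT library 2 against 213.4 to 214.7. Ptch1 was at 44.0 CPM in WT library 1 against 47.7 to 48.2, and Cnn1 at 5.86 CPM in WT library 2 against 4.31 to 4.34.

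Long transcripts were lower in KO libraries 2 and 3, and 3 of the called lists were examined against that trend. The correction for length and GC left the matrix genes at a median of -0.39 (95% bootstrap interval -0.59 to -0.30) and the cell cycle genes at -0.36 (-0.46 to -0.28). Both stayed past the threshold with camera, at adjusted p = 0.0442 with an estimated correlation, which argues against the trend as the whole cause. The bootstrap intervals were drawn over the genes of a list, taken as independent, and do not measure the spread between libraries. A loss of stromal fibroblasts would remove Dcn and Lum together with Col1a1. Dcn, at 0.517 CPM in WT, was no lower in KO (0.69 CPM). Lum fell from 0.310 CPM in WT to 0.0577 in KO (edgeR adjusted p = 0.0762). As shares of the Col1a1 loss of 48.3 CPM, their losses were -0.360% and 0.523%. With both genes this far below Col1a1 (72.7 CPM) in WT, even their full loss would be a small share. These shares therefore cannot test a loss of fibroblasts. The level of Dcn speaks only to fibroblasts rich in Dcn, and Lum moved the other way. A loss of stromal fibroblasts thus stays open. Smooth muscle and pericyte markers fell too (list median -0.64), and a change in the share of other collagen-making cells was not tested. The Hippo components moved from -0.26 (-0.33 to -0.14) to -0.12 (-0.16 to -0.0202) because the correction took out much of their fall (camera adjusted p = 0.152), so trend and genotype cannot be told apart for that list. The KO slopes spanned 6.21 times the range of the WT slopes, which RNA or library quality might produce; with KO library 1 outside the WT range too, it cannot be told apart from an effect of genotype, which stays open.

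Wdfy1, Gm42031 and Nnt, the latter pair picked after their values were seen, were lower in all 3 KO libraries than in any WT library, with Gm42031 at 6.47 ± 0.730 CPM in WT (SD, n = 4) and 0.0941 ± 0.0885 in KO (SD, n = 3). A stretch of chromosome 1 from another strain, carried along with the Fhl2 allele, was examined by the genes near Fhl2. Within 10 Mb of Fhl2, 2 of 100 genes changed at least 2-fold and 324 of 15473 elsewhere, a ratio of shares of 0.955. No excess was thus seen in that window. Wdfy1 lies 36.5 Mb away on the same chromosome, and a stretch that reaches it was not tested. Gm42031 lies on chromosome 8, outside any such stretch, and Nnt had no coordinates here. Nnt, part of which is deleted in C57BL/6J but not in C57BL/6N mice, changed by -0.89 on the log2 scale, which could come from a difference in substrain, although the labels give C57BL/6J for all samples. A count per gene does not show the deleted exons, so a substrain difference and an effect of the Fhl2 knockout cannot be told apart for these genes. A substrain difference, if there was one, would follow genotype in all libraries. It could then bear on the other calls and lists as well, which was not tested.

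KO libraries 1 and 2 held reads of lung genes: 12 such genes together had 515 and 1512 reads there, 63 in KO library 3 and 9 to 34 in the WT libraries. Of 7 lung genes not looked at before, 5 lay above the WT libraries in both, but only 2 of these had at least 20 reads in KO library 1, and their median ratio of KO 2 to KO 1, 0.887 of that of Sftpc, was that of Cyp2f2 with 1 and 3 reads. Over all 7 lung genes with at least 20 reads in KO library 1, the CPM ratio of KO 2 to KO 1 ran from 2.03 to 2.92. Apart from the 2 above, these genes had been looked at before. Ager, with 18 and 23 reads, had a ratio of 1.10. Whether the reads had 1 source, and of what kind, stays open: Slc34a2 had 55 and 187 reads and, of the airway genes, Scgb1a1 had 55 and 160, Scgb3a1 2 and 25 and Scgb3a2 0. The rise of epithelial keratins is not accounted for by these reads as a whole, because 3 of the 3 keratins Krt7, Krt19 and Krt18 also lay above every WT library in KO library 3. Whether the keratins rose through the Fhl2 knockout or through a share of other epithelial cells was not tested. Leaving out the 12 lung genes gave 4586 genes past the threshold. That setting tested 15795 genes against 15798 in the main fit, so the count could hardly change. Any other transcripts from the source of the lung reads stayed in, so the count does not show how far that source bears on the calls.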

How the results depend on the processing

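The corrections for length, KO library 1 alone and the removal of lung genes were chosen after seeing the data; the other alternatives were planned. Fhl2 stayed lower and past the threshold under the 19 alternatives in which it was tested, from -1.17 to -0.74 on the log2 scale. The number of genes past the threshold ranged from 1657 (without KO library 3) to 6740 (without KO library 1) when a library was left out, the 2-fold count from 244 (without KO library 3) to 579 (without KO library 1), the list count from 10 to 12 and Fhl2 from -0.98 to -0.74. Without WT library 3 and WT library 4, 2994 and 2960 genes passed. Same-numbered libraries did not deviate together (correlations of 0.0326, -0.00130 and -0.0324), so the counts gave no sign that the numbers pair the samples. Deviations from the mean of so few libraries, with a length trend among those of KO, cannot exclude a pairing. With the replicate number as a block, which leaves out WT library 4, 3301 genes, 352 genes at 2-fold and 13 lists passed, with the ERK-responsive (camera adjusted p = 3.22e-04) and inflammatory genes (7.59e-07) among them (0.463 and 0.318 with an estimated correlation), and Fhl2 was at -0.89; the same 6 libraries without the block gave 2960 genes. The highest correlation was with WT library 1 for KO library 1 (0.0326), WT library 3 for KO library 2 (0.00945) and WT library 2 for KO library 3 (0.0994). These values are too weak to mark pairs.

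The 2-fold count was 536 with voom quality weights, where the cause was not tested, and 79 with the filter of 10 CPM, which leaves 9203 genes. KO library 1 alone against WT gave 781 genes and 135 at 2-fold, with fewer samples. Camera with an estimated correlation gave 0 lists, or 6 after the length and GC correction, where the cause was not tested, and fry, which does not compare a list with other genes, 17. Taok1 changed sign under the length and GC correction (0.10, edgeR adjusted p = 0.385) and under length alone (0.11, 0.438). So did the test of mitochondrially encoded mRNAs, with medians of -0.40 and -0.37 (camera adjusted p = 0.00187 and 0.0151, or 0.338 and 0.378 with an estimated correlation); the corrections remove a trend under which short transcripts are higher in KO. Sign changes are counted where either value passed the threshold. Of the 11 lists, 8 stayed past the threshold with adjusted p up to 0.00794 under the 18 or 19 alternatives run for each, apart from those with an estimated correlation. Of 113 named genes past the threshold, 47 lost or reversed the call under some alternative, 20 lost it without some library, 13 lost or reversed it under the length and GC correction and 41 with KO library 1 alone, which has fewer samples. Depth of at least 38855596 counts leaves genes near 3 counts per library undecided.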

Other observations

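Of the tests given here, that of the NRF2 target genes and the counts of other splits were set before their results were seen. Several genes of glutathione use and redox control, picked after their values were seen, were higher in the KO libraries. Gpx3, a secreted glutathione peroxidase, went from 167.3 ± 6.67 CPM in WT (SD, n = 4) to 417.7 ± 70.0 in KO (SD, n = 3; log2 fold change 1.32, SE 0.104, edgeR adjusted p = 3.26e-07). Gsta4 rose from 26.1 ± 1.86 to 54.9 ± 6.87 CPM, and Gsta3 (log2 fold change 1.55, SE 0.199), Nqo1 (1.30, SE 0.227) and Osgin1 (1.35, SE 0.157) rose from low levels. The hypothesis that targets of the transcription factor NRF2 rose as a group was tested on 19 target genes not looked at before. Of these, 11 were higher and 1 was lower (edgeR), with a median log2 fold change of 0.42 (95% bootstrap interval over the genes 0.05 to 0.54) and camera p = 6.00e-06, or p = 0.0312 with an estimated correlation. Corrected for length and GC content, 14 were higher and 0 lower, with a median of 0.29; the median was 0.26 for KO library 1 alone against WT and 0.51 without it. Malic enzyme Me1 (log2 fold change 0.88, SE 0.0922) and the heme oxygenase Hmox1 (0.69, SE 0.0894) were among those higher, while the glutamate-cysteine ligase subunits Gclc (-0.10, SE 0.101) and Gclm (-0.02, SE 0.0938), classical targets, did not pass. The member that was lower, the cystine transporter subunit Slc7a11 (-0.53, SE 0.153, edgeR adjusted p = 0.0167; corrected -0.13), is a classical target too. The values are consistent with a rise of part of this group, and the activity of NRF2 itself was not measured.

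Other genes with large changes were picked after their values were seen. The retinoic acid-making enzyme Aldh1a2 rose from 1.49 ± 0.237 CPM in WT (SD, n = 4) to 4.46 ± 0.808 in KO (SD, n = 3), next to the retinol dehydrogenases Adh1 and Adh7. The plasminogen activator Plau rose from 331.3 ± 30.8 to 776.1 ± 86.0 CPM. The insulin-degrading enzyme Ide fell from 188.3 ± 10.6 to 117.6 ± 5.96 CPM.

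The 7 libraries can be split into 3 and 4 in 35 ways. The real split gave 4588 genes past adjusted p 0.05 with edgeR and the highest other split 1, so 1 of the 35 splits gave as many. That is the smallest share that 35 splits can give. Each of the other splits puts WT and KO libraries into 1 group, so any difference between them adds to the spread within that group. The gene counts of the other splits thus do not measure how many calls chance alone would give. For genes at least 2-fold changed the values were 335 and 1, again 1 of 35. For gene lists the real split gave 11 with camera and the highest other 12, and 5 of the 35 splits gave as many, so chance cannot be excluded for the number of lists. Among these splits, 2 set 3 WT libraries against the rest and 2 set KO libraries 1 and 2 with 1 WT library against the rest, so they keep part of the genotype contrast. List by list, the real split alone gave as small a camera p for matrix, Hippo, steroid, stroma and luteal genes, and also for theca markers, which did not pass (camera p of 0.357). The next smallest p came close for Hippo (1.02e-04 against 1.28e-04), stroma (1.99e-05 against 2.40e-05) and matrix genes (1.97e-13 against 6.13e-13), so the rank alone separates little there. The number of splits was 2 for cell cycle and smooth muscle genes, 3 for actin and surface epithelium genes, 7 for interferon-stimulated genes and 8 for cholesterol genes.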
